A study of Mus musculus with 6 samples.

How the data were processed

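Poly(A) RNA from liver was sequenced from 6 mice, 1 library per mouse, 3 wild-type and 3 Cd44 knockout; groups were taken from the genotype in the labels. RNA was copied with random hexamer primers, and no step that marks strand is described, per the labels' protocols. The values are raw counts of reads per Ensembl gene, as deposited by the authors, with 1 column per mouse and no normalisation. HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 on GRCm38.p6 are named, per the submitters' processing notes; the annotation release, strand setting and treatment of multi-mapping reads are not given in the sources used here. Reads from overlapping genes and from near-identical copies therefore cannot be assigned with certainty. Some close copies are marked where named, and other named genes that belong to gene families, such as Ifit3 and Cyp2b10, may be affected too. Of the named genes, Igtp, Fdft1, Ncf1, Tap1, Timp1, Cxcl10 and Hk3 overlap a gene with many counts and are uncertain for this reason; other named genes that overlap a gene model share it with few counts. Of 54682 rows, 54495 matched a gene of the GENCODE annotation of the same build, used for symbols, positions and biotypes; 150 rows were gene models with no gene name, which held 0.273% to 0.509% of the counts of a library and were left out of library sizes and of the main tests.

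Total counts ran from 15493009 to 19346623 per library. At these depths 3 counts, the limit that a count of 0 allows, correspond to 0.155 to 0.194 CPM; intervals and this floor cover counting error only. Mice were taken as the replicates, since the labels name separate mice.

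Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries scaled by TMM, and genotype tested with the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment over 14145 genes and a threshold of 0.05. The standard error is the fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.237. DESeq2 1.42.0 and limma 3.58.1 (voom) were alternatives. With 3 against 3 mice an exact permutation test of a single value cannot go below p = 0.1, so p values for genes come from these models. On simulated counts (14145 genes, 200 changed, 5 runs), the edgeR fit recovered 43.6% of 2-fold and 86.4% of 4-fold changes with 9.72% false calls, and DESeq2 58.8% and 90.6% with 21.8% false calls.

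Of 43 gene lists fixed before the data were examined, 41 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 41 lists, with camera at an estimated correlation and fry beside it; the Y-linked and X-inactivation genes and the pancreatic acinar genes had 1 tested member each and were not tested. Lists share members: 5 of the 23 monocyte and infiltrating macrophage genes and 10 of the 32 extracellular matrix and fibrosis genes are also in another list, and Spp1 is in several. For each list, members were counted in edgeR at an adjusted p under 0.05 over all genes and adjusted over the list alone. DESeq2 calls over all genes are given where there were any. Genes within 10 Mb of Cd44 were compared with the rest by a two-sided Fisher's exact test.

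Genes were named by a rule fixed before the data were examined: Cd44; the genes past the threshold with mean log2 CPM of at least 1, a protein-coding biotype and no overlap between groups, up to 10 in each direction; up to 4 members of a list by smallest p; and a fixed set of 28 genes for alcohol-fed liver. Any gene outside it is said to be chosen after its values were seen, as also holds for Thbs1. Alternatives were another normalisation (RLE), no low-count filter, a filter of CPM of at least 1 in 3 libraries, mouse number as a block, the older non-robust quasi-likelihood fit, DESeq2, limma-voom, a threshold of 0.01, a fold-change minimum, protein-coding genes only, camera on ranks, other windows around Cd44, and leaving out each library in turn.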

Results

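Liver RNA was sequenced from 6 mice, 3 wild-type and 3 homozygous for a targeted Cd44 allele kept on the C57BL/6 background. Cd44 encodes a cell surface receptor for hyaluronan and osteopontin that is carried by many leukocytes. Each mouse had a Lieber-DeCarli liquid diet with 5% ethanol by volume for 10 days, then 5 g/kg ethanol by gavage on day 11, and livers were taken 9 hours later. This is a chronic-plus-binge model of alcohol-related liver injury. All 6 mice had ethanol, so the comparison asks how the ethanol-exposed liver differed between genotypes, and a mouse without ethanol was not analysed here. Reads assigned to annotated genes came to 18006959, 16083334 and 17892549 in wild-type mice 1, 2 and 3, and to 15429784, 19293777 and 15848616 in knockout mice 1, 2 and 3. Fold changes are knockout relative to wild-type on the log2 scale, followed by their standard error, and levels are CPM, counts scaled to the TMM-normalised library size, as mean ± SD with n = 3 per genotype.

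Cd44 transcripts were nearly absent from the knockout livers. Cd44 (ENSMUSG00000005087; GRCm38, chromosome 2, 102811141 to 102901665, minus strand) had 590, 175 and 568 counts in the 3 wild-type libraries and 1, 0 and 0 counts in the 3 knockout libraries. The level was 24.2 ± 11.1 CPM in wild-type mice, and the counts summed over each genotype gave a wild-type to knockout ratio of 1297 (95% interval from counting error alone 232 to 51260). The gene was lower by edgeR's quasi-likelihood test (log2 fold change −9.78 ± 0.77, adjusted p = 0.00647), and no library went against its genotype label. The call depended on the number of knockout libraries: the adjusted p was 0.331, 0.0977 and 0.158 without knockout 1, 2 and 3, and 0.283 with limma-voom.

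**Figure D1:**
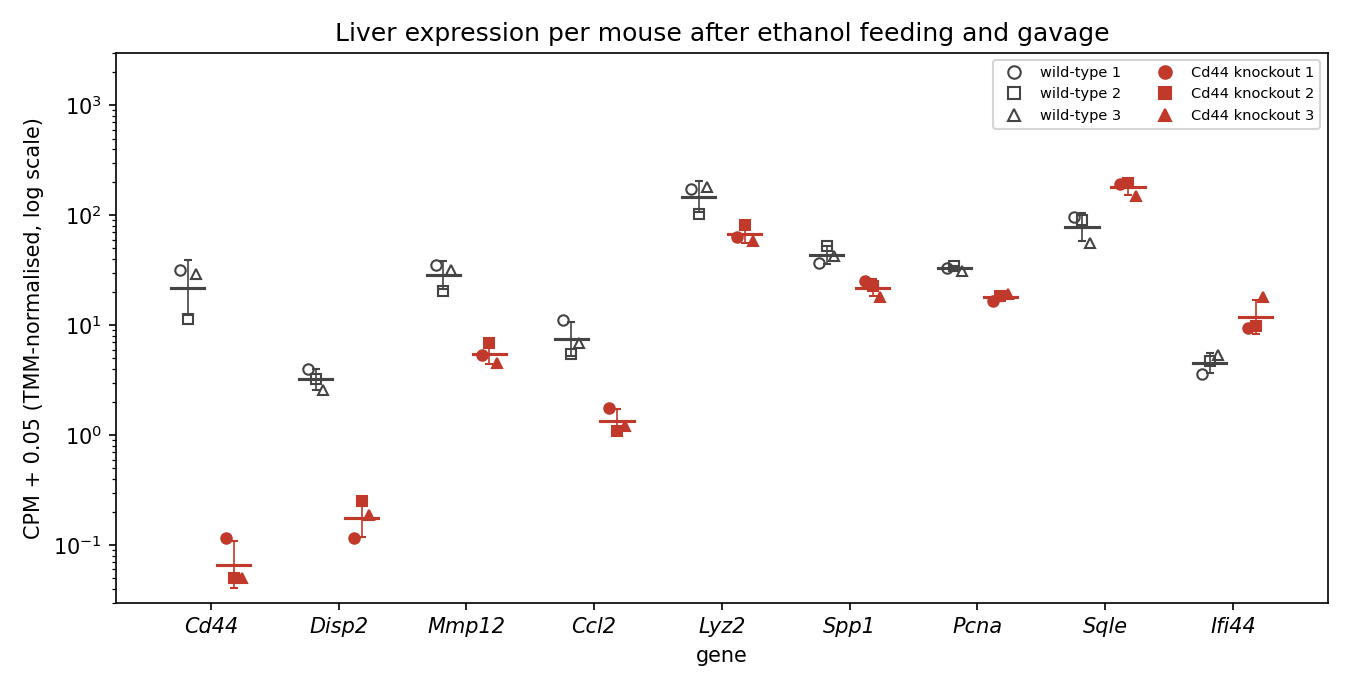
TMM-normalised CPM plus 0.05, on a log axis, of 9 genes in each of the 3 wild-type (open symbols) and 3 knockout livers (filled symbols); horizontal lines are means of the log values and bars 1 SD. Cd44 and Disp2 passed the threshold over all genes; the other 7 genes did not, although their wild-type and knockout values do not overlap.

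Few single genes passed the edgeR threshold over all genes with 3 mice per genotype. Of 14145 genes tested, 2 passed an adjusted p of 0.05 in edgeR, Cd44 and Disp2, and both were lower in the knockout. Disp2, a homolog of the Drosophila dispatched gene (ENSMUSG00000040035; chromosome 2, 118779719 to 118811293), fell from 3.24 ± 0.712 to 0.135 ± 0.067 CPM (log2 fold change −4.46 ± 0.44, adjusted p = 0.0316). Disp2 lies outside the rule for named genes because of its low level and was chosen after its values were seen; it lies 16.0 Mb from Cd44 on the same chromosome. Mmp12, the macrophage metalloelastase (ENSMUSG00000049723; chromosome 9, 7344381 to 7369499), came next at 29.1 ± 7.83 CPM in wild-type and 5.54 ± 1.22 CPM in knockout livers (log2 fold change −2.39 ± 0.25, adjusted p = 0.0607). Below an unadjusted p of 0.05 lay 1812 genes, of which 739 were higher and 1073 lower in the knockout, where chance gives about 707. Other splits of the 6 libraries into 3 and 3 gave 278 to 1173 such genes, a wide spread around 707. Each of these splits mixes the genotypes and can carry part of a difference between them, so the spread is no pure measure of chance. The values of the genotypes did not overlap for 2578 genes, 18.2% of those tested, where chance gives 10%. The count of calls depended on the tool and on single libraries: DESeq2 called 287 genes (99 higher, 188 lower) and limma-voom 0, and edgeR called 151 without wild-type 2, 1 without knockout 1 and 0 without knockout 2 or without knockout 3. Disp2 had an adjusted p of 0.0874 without wild-type 1 and of 0.331, 0.157 and 0.626 without knockout 1, 2 and 3.

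Gene lists fixed before the data were examined were compared with camera, which asks whether a list's genes shift more than the other genes. With a preset correlation between genes of 0.01, 19 of 41 lists passed an adjusted p of 0.05, 14 lower and 5 higher in the knockout. With a correlation estimated from these 6 libraries 0 lists passed (5 had an unadjusted p under 0.05), and fry, which tests whether a list's genes move one way, gave a smallest adjusted p of 0.0776. The mixed form of fry asks for change in either direction. It passed only for cholangiocyte (adjusted p = 0.00655), CD44 ligand and partner (0.0269) and cytokine and chemokine genes (0.0362). In 10 of the 41 lists the medians of the 3 wild-type mice did not overlap those of the 3 knockout mice, where chance gives 10% of lists; 9 of them were among the 19. The genotypes overlapped for the neutrophil, Kupffer cell, toll-like receptor and NF-kB, inflammasome, cell cycle, immediate early, NRF2, secreted protein, xenobiotic cytochrome P450 and pericentral lists. The same camera test called between 8 and 25 lists in the other splits of the 6 libraries into 3 and 3, which mix the genotypes and so are no pure measure of chance. The split by genotype gave the smallest p of the 10 splits for 4 of all 41 lists, where chance gives 10%. These were monocyte and infiltrating macrophage genes, dendritic cell genes, cholangiocyte genes, and cytokine and chemokine genes, all among the 19. The list calls described next rest on the preset correlation and carry this limit.

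**Figure D2:**
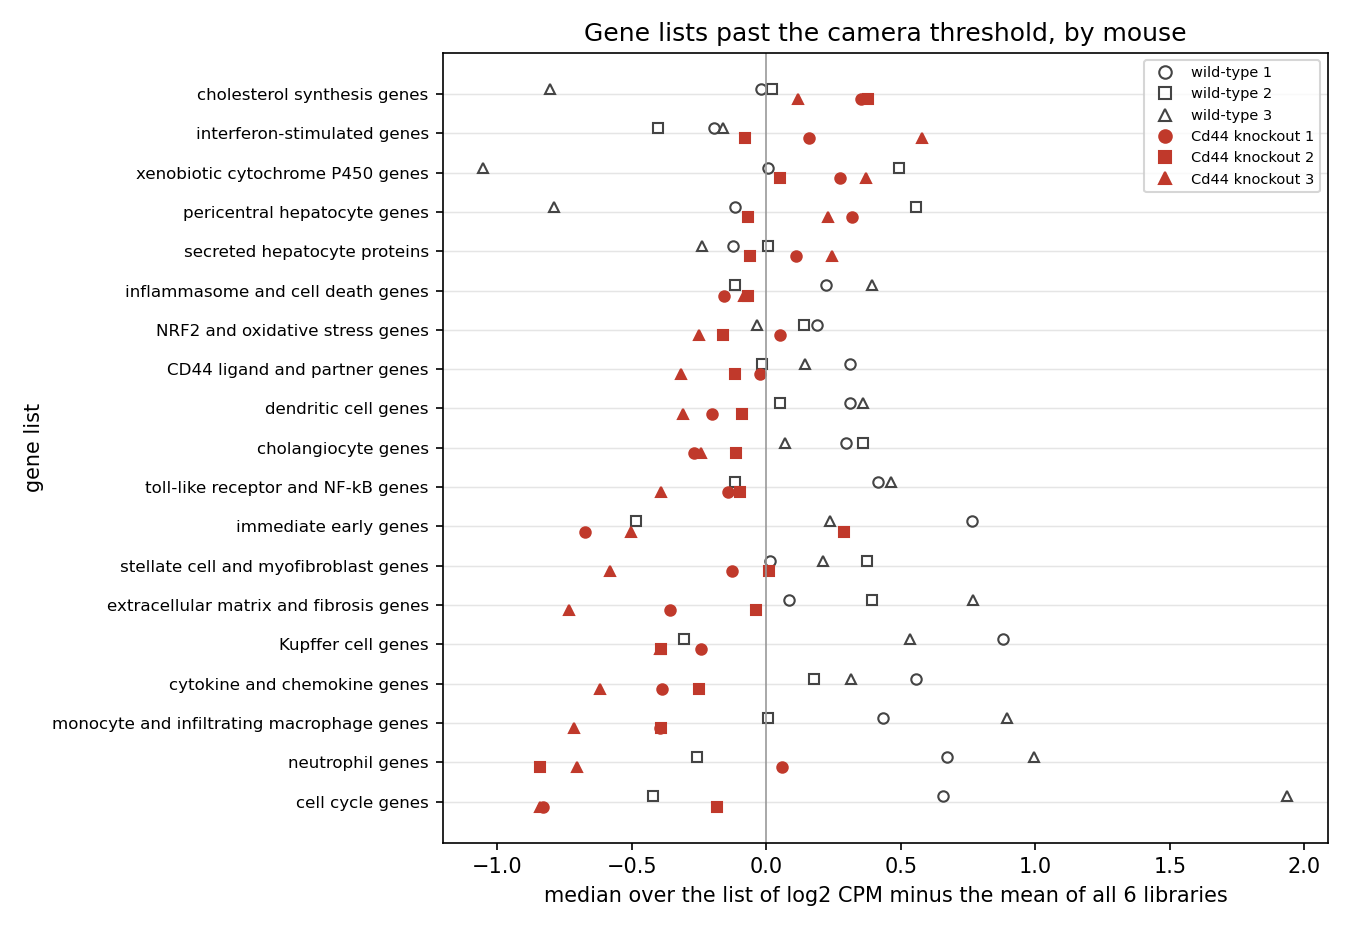
Median over each list's genes of the log2 CPM minus the mean of all 6 libraries (x axis), for the 19 gene lists past the camera threshold (y axis), with 1 symbol per mouse. Monocyte and infiltrating macrophage genes were above 0 in all 3 wild-type mice (open symbols) and at −0.39, −0.39 and −0.72 in the knockout mice (filled symbols), and wild-type 3 lies apart at 1.94 for cell cycle genes.

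Macrophage genes were lower in the knockout livers. Of 23 tested monocyte and infiltrating macrophage genes, 21 had a lower mean in the knockout and the median log2 fold change was −1.04 (camera adjusted p = 3.15e-17; adjusted p = 0.253 with an estimated correlation). No member passed over all genes in edgeR, while DESeq2 called 7, all lower. Adjusted over the list alone, 15 were lower in edgeR. Among these were Lyz2, the myeloid lysozyme (152 ± 43.9 against 67.8 ± 12.0 CPM, log2 fold change −1.17 ± 0.24), Lgals3, or galectin-3 (21.5 ± 9.97 against 5.95 ± 1.64 CPM, −1.85 ± 0.38), Spp1, which encodes the CD44 ligand osteopontin (43.8 ± 8.19 against 22.2 ± 3.75 CPM, −0.98 ± 0.18), and Sirpa, the receptor for CD47 (52.5 ± 14.9 against 21.9 ± 2.25 CPM, −1.26 ± 0.22), which lies 26.8 Mb from Cd44. Reads of Lyz2 and its near-identical neighbour Lyz1 can be split by the counting. Genes of Kupffer cells, the resident macrophages of the liver, were lower in 20 of 21 cases with a median of −0.86 (adjusted p = 5.01e-11; adjusted p = 0.360 with an estimated correlation). Over all genes 0 of its members passed in edgeR, while DESeq2 called 4, all lower. Adjusted over the list alone, 11 passed in edgeR, all narrowly at the same adjusted p of 0.0448. They included Vsig4, a complement receptor (−1.22 ± 0.30), Cd5l, a secreted macrophage protein (−1.91 ± 0.50), and Adgre1, which encodes F4/80 (−1.56 ± 0.42). Clec4f, also a Kupffer cell marker, gave 125 ± 48.5 against 81.0 ± 5.72 CPM (−0.62 ± 0.28, adjusted p = 0.415). Wild-type 2 lay with the knockout mice for the Kupffer cell list, at a median of −0.30 from the mean of all libraries against 0.88 and 0.53 in wild-type 1 and 3. All 14 tested dendritic cell genes had a lower mean in the knockout (median −0.42, adjusted p = 0.000564; adjusted p = 0.236 with an estimated correlation). Of its members, 0 passed when adjusted over the list alone and 0 over all genes, while 4 had an unadjusted p under 0.05, all lower. The integrin Itgax gave −1.19 ± 0.35 and the transcription factor Irf8 −0.79 ± 0.24.

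Chemokine and inflammatory signalling genes were lower alongside the macrophage genes. Of 25 cytokine and chemokine genes tested, 22 had a lower mean. They had a median log2 fold change of −0.98 (camera adjusted p = 4.4e-13; adjusted p = 0.236 with an estimated correlation). Of its members, 12 passed in edgeR when adjusted over the list alone and 0 over all genes. DESeq2 called 5 over all genes, all lower. Ccl2, the monocyte chemoattractant (chromosome 11, 82035571 to 82037453), was at 7.80 ± 2.93 CPM in wild-type and 1.31 ± 0.361 CPM in knockout livers (−2.58 ± 0.35), the neutrophil chemoattractant Cxcl2 at 1.92 ± 0.367 and 0.317 ± 0.300 CPM (−2.63 ± 0.54; −3.66 without knockout 1), and the CXCR3 ligand Cxcl10 at 15.8 ± 6.17 and 5.08 ± 0.568 CPM (−1.63 ± 0.30), uncertain because it overlaps Art3 on the opposite strand. Cxcl1, also a neutrophil chemoattractant, was not lower, at 13.4 ± 7.29 and 15.5 ± 16.0 CPM (0.20 ± 0.78, adjusted p = 0.949). Its highest value was 33.9 CPM in knockout 1. Tnf (−1.66 ± 0.54, adjusted p = 0.277) and Il1b (−1.47 ± 0.42, adjusted p = 0.239) did not pass over all genes. The toll-like receptor and NF-kB genes had a median of −0.48 (24 of 28 lower, adjusted p = 4.77e-07; adjusted p = 0.360 with an estimated correlation). Over all genes 0 of its members passed in edgeR, while DESeq2 called 6, all lower. Adjusted over the list alone, 7 passed in edgeR. These included the receptor Tlr2 (−1.02 ± 0.25), the NF-kB inhibitor Tnfaip3 (−1.55 ± 0.37) and the adhesion molecule Vcam1 (−1.11 ± 0.24). The 9 tested neutrophil genes were all lower in mean (median −1.15, adjusted p = 1.59e-05; adjusted p = 0.360 with an estimated correlation). Of its members, 3 passed when adjusted over the list alone, and 0 over all genes. The former were Mmp9, S100a9 and Ncf1, with wild-type means of 1.11, 1.72 and 8.15 CPM; Ncf1 overlaps Gtf2ird2 on the opposite strand and is uncertain. Lcn2, an acute-phase and neutrophil gene, reached 1528 CPM in wild-type 3 and 61.6 to 189 CPM in the other libraries, and its log2 fold change of −2.42 ± 1.09 became −0.28 without wild-type 3. Inflammasome and cell death genes passed narrowly (median −0.24, adjusted p = 0.0416; adjusted p = 0.668 with an estimated correlation). Of its members, 0 passed in edgeR when adjusted over the list alone and 0 over all genes, while 6 lower and 1 higher had an unadjusted p under 0.05. DESeq2 called 2 over all genes, both lower. Ripk3 gave −1.77 ± 0.40 and Nlrp3 −2.02 ± 0.55 (−1.42 without wild-type 1). The camera call of the list was lost without wild-type 1 (adjusted p = 0.150), wild-type 3 (0.363), knockout 1 (0.0912) or knockout 2 (0.0713), and with camera on ranks (0.0765).

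Genes of the extracellular matrix were lower in the knockout livers. Of 32 extracellular matrix and fibrosis genes, 31 had a lower mean in the knockout, with a median log2 fold change of −0.80 (camera adjusted p = 3.38e-18, and 0.253 with an estimated correlation). Over all genes 0 of its members passed in edgeR, while DESeq2 called 7, all lower. Adjusted over the list alone, 9 passed in edgeR. Beside Mmp12 these included the metalloproteinase inhibitor Timp1 (2.48 ± 1.07 against 0.423 ± 0.250 CPM, −2.50 ± 0.52; uncertain, as it overlaps Syn1 on the opposite strand), the collagen gene Col5a1 (21.3 ± 3.64 against 10.8 ± 1.71 CPM, −0.98 ± 0.18) and the thrombospondin Thbs1 (−2.10 ± 0.44), which lies 15.3 Mb from Cd44 and was chosen after its values were seen. The main fibrillar collagens did not pass over all genes in edgeR: Col1a1 gave −1.30 ± 0.50 (adjusted p = 0.356, and −0.69 without wild-type 3) and Col3a1 −1.47 ± 0.46 (adjusted p = 0.277). DESeq2 called Col3a1 (adjusted p = 0.0155) and not Col1a1 (0.0667). Genes of stellate cells and myofibroblasts, the collagen-producing cells of the liver, had a median of −0.64 (adjusted p = 0.00105; adjusted p = 0.360 with an estimated correlation; 0.0727 without wild-type 2). Of its members, 1 passed in edgeR when adjusted over the list alone, Timp1, and 0 over all genes, where DESeq2 called 2, both lower. Cholangiocyte genes were lower in 15 of 16 cases (median −0.43, adjusted p = 0.000891; adjusted p = 0.236 with an estimated correlation). Of its members, 1 passed in edgeR when adjusted over the list alone, Spp1, and 0 over all genes, where DESeq2 called 1, lower. Anxa5 gave −0.86 ± 0.27 and Clu −0.54 ± 0.20, and both genes are also active in other liver cells. The CD44 ligand and partner genes had a median of −0.30 (adjusted p = 0.0015; adjusted p = 0.360 with an estimated correlation; 0.0595 without wild-type 1). Of its members, 3 passed in edgeR when adjusted over the list alone (Spp1, Mmp9 and the membrane linker Ezr at −0.81 ± 0.21) and 0 over all genes. DESeq2 called 1 over all genes, lower. Met, the hepatocyte growth factor receptor, went the other way (0.49 ± 0.15, adjusted p = 0.249).

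Proliferation genes were lower in the knockout livers, with a wide spread between wild-type mice. Of 26 cell cycle genes, 25 had a lower mean and the median log2 fold change was −1.85 (camera adjusted p = 4.4e-13; adjusted p = 0.360 with an estimated correlation). Over all genes 0 of its members passed in edgeR, while DESeq2 called 8, all lower. Adjusted over the list alone, 8 passed in edgeR. Pcna, the DNA polymerase clamp, was at 33.0 ± 1.91 CPM in wild-type and 18.1 ± 1.37 CPM in knockout livers (−0.87 ± 0.12); it lies 29.4 Mb from Cd44. The replication licensing genes Mcm3 (−1.20 ± 0.23) and Mcm5 (−1.93 ± 0.38) and the transcription factor E2f1 (−1.47 ± 0.36) were also among the 8 in edgeR. The list's median stood at 1.94 above the mean of all libraries in wild-type 3, at 0.66 in wild-type 1 and at −0.42 in wild-type 2, which lay below knockout 2 at −0.18; the list's median log2 fold change was −0.92 without wild-type 3. Immediate early genes had a median of −0.55 (adjusted p = 0.00097; adjusted p = 0.604 with an estimated correlation). Of its members, 2 passed in edgeR when adjusted over the list alone, Ier3 (−1.50 ± 0.29) and Egr2 (−1.65 ± 0.39), and 0 over all genes. DESeq2 called 5 over all genes, all lower. The camera call of the list was lost without wild-type 1 (adjusted p = 0.315) or knockout 1 (0.0980). The NRF2 and oxidative stress genes had a median of −0.25 (adjusted p = 0.000221; adjusted p = 0.360 with an estimated correlation). Over all genes 0 of its members passed in edgeR, while DESeq2 called 2, both lower. Adjusted over the list alone, 2 passed in edgeR. These were the glutathione transferases Gsta4 (−0.60 ± 0.13) and Gstp2 (−2.43 ± 0.42), the latter uncertain because its reads can be shared with Gstp1. Nqo1, a quinone reductase, gave −0.57 ± 0.16 (adjusted p = 0.231).

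Interferon-stimulated and cholesterol synthesis genes were higher in the knockout livers. Of 28 interferon-stimulated genes, 25 had a higher mean, with a median log2 fold change of 0.47 (camera adjusted p = 5.01e-11, and 0.360 with an estimated correlation). Over all genes 0 of its members passed in edgeR, while DESeq2 called 6, all higher. Adjusted over the list alone, 9 passed in edgeR. They included Ifi44 (4.53 ± 0.919 against 12.4 ± 4.85 CPM, 1.45 ± 0.30), Ifit3 (14.5 ± 2.55 against 27.2 ± 6.49 CPM, 0.91 ± 0.21), Usp18, which removes ISG15 from proteins (1.03 ± 0.26), and the immunity-related GTPase Igtp (1.16 ± 0.22), whose gene model overlaps that of Irgm2 on the same strand and whose value is uncertain. Knockout 3 stood highest for the list, at a median of 0.58 from the mean of all libraries against 0.16 and −0.08 in knockout 1 and 2, and the list's median log2 fold change was 0.28 without it (adjusted p = 3.53e-07). All 25 cholesterol synthesis genes had a higher mean (median 0.48, adjusted p = 7.1e-11; adjusted p = 0.360 with an estimated correlation). Over all genes 0 of its members passed in edgeR, while DESeq2 called 2, Sqle and Lss. Adjusted over the list alone, 4 passed in edgeR. These were squalene epoxidase Sqle (80.9 ± 21.7 against 181 ± 25.8 CPM, 1.16 ± 0.22), lanosterol synthase Lss (36.5 ± 0.644 against 62.5 ± 9.55 CPM, 0.78 ± 0.14), Hsd17b7 (0.61 ± 0.16) and Fdft1 (0.79 ± 0.22), which overlaps the abundant gene Ctsb on the opposite strand and is uncertain. The list was lowest in wild-type 3, at −0.80 from the mean of all libraries, and its median log2 fold change was 0.19 without that mouse (adjusted p = 1.72e-06).

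Of the hepatocyte lists, those of secreted proteins, xenobiotic cytochrome P450 genes and pericentral genes were higher in the knockout with smaller medians, and periportal genes did not pass. The secreted hepatocyte proteins had a median of 0.21 (21 of 24 higher, adjusted p = 0.00159; adjusted p = 0.541 with an estimated correlation). Of its members, 0 passed when adjusted over the list alone and 0 over all genes, while 1 lower and 4 higher had an unadjusted p under 0.05. The fibrinogen genes Fgb (0.72 ± 0.27) and Fgg (0.69 ± 0.28) were higher in mean and transferrin Trf was lower (−0.43 ± 0.15, adjusted p = 0.301). Xenobiotic cytochrome P450 genes had a median of 0.33 (24 of 28 higher, adjusted p = 0.00159; adjusted p = 0.541 with an estimated correlation). Of its members, 0 passed when adjusted over the list alone and 0 over all genes, while 1, higher, had an unadjusted p under 0.05. Cyp2b10, a target of the nuclear receptor CAR, gave 0.70 ± 0.28. The pericentral hepatocyte genes had a median of 0.25 (adjusted p = 0.0347; adjusted p = 0.714 with an estimated correlation). Of its members, 0 passed when adjusted over the list alone and 0 over all genes, while 2, both higher, had an unadjusted p under 0.05. The aryl hydrocarbon receptor Ahr gave 0.49 ± 0.14 and the Wnt target Axin2 0.63 ± 0.23. Wild-type 3 lay lowest for the last pair of lists, at −1.05 and −0.79 from the mean of all libraries. Without it the adjusted p was 0.242 for the xenobiotic cytochrome P450 genes and 0.852 for the pericentral hepatocyte genes, whose median log2 fold change then was −0.09; the pericentral call was also lost without wild-type 1 (0.0906) or knockout 1 (0.250).

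Lists of other cell types did not pass: T and NK cell genes (adjusted p = 0.961), B and plasma cell genes (0.397), liver endothelial genes (0.452), erythroid and platelet genes (0.167), adipocyte and mesothelial genes (0.277) and muscle genes (0.857). Of the metabolic lists, periportal hepatocyte genes (0.235), ethanol metabolism and detoxification genes (0.344), lipogenesis genes (0.808), bile acid synthesis and transport genes (0.258) and amino acid and urea cycle genes (0.108) did not pass either. Acute-phase genes (0.344), circadian clock genes (0.397), mitochondrially encoded genes (0.110), ribosomal protein genes (0.265), male-biased liver genes (0.0853) and female-biased liver genes (0.154) were also short of the threshold. None of these lists had a member that passed in edgeR over all genes or adjusted over the list alone. DESeq2 called 2 periportal genes and 1 acute-phase gene over all genes, all lower. The median log2 fold change was below 0 while camera's direction was up for lipogenesis genes (−0.12) and muscle genes (−0.50), and the mean of acute-phase genes was −0.05 with a median of 0.08. Wild-type 3 was at −1.05 for lipogenesis genes and −1.99 for female-biased liver genes; without it the lipogenesis genes were lower in the knockout (median −0.31, adjusted p = 2.27e-05), as were liver endothelial genes (adjusted p = 0.000425), glycolysis and gluconeogenesis genes (0.000630) and erythroid and platelet genes (2.76e-06), while ribosomal protein genes (0.00136) and amino acid and urea cycle genes (0.000669) were higher. Other left-out libraries also brought calls. Without wild-type 2 lipogenesis genes passed with a median of 0.23 (adjusted p = 0.0412), as did ethanol metabolism (0.0412), B and plasma cell (0.00237), bile acid (0.00979), mitochondrially encoded (0.0260), circadian (0.0472), female-biased (0.00156) and amino acid genes (0.0407). Without knockout 2 acute-phase (0.0128), male-biased (0.00288), mitochondrially encoded (0.00227), amino acid (0.00481) and adipocyte genes (0.0453) passed. Periportal genes passed without wild-type 1 (0.0275) or knockout 3 (0.0359), adipocyte genes without wild-type 1 (0.0275) and B and plasma cell genes without knockout 1 (0.0423). Amino acid genes passed with no low-count filter (0.0498) and female-biased genes with the mouse number as a block (0.0285).

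Ethanol-metabolising enzymes did not pass in edgeR. Cyp2e1, the ethanol-inducible cytochrome P450, was at 2357 ± 1580.4 CPM in wild-type and 2864 ± 725 CPM in knockout livers (0.28 ± 0.45, adjusted p = 0.859), alcohol dehydrogenase Adh1 gave 0.18 ± 0.18 (adjusted p = 0.745) and aldehyde dehydrogenase Aldh2 0.21 ± 0.24 (adjusted p = 0.781). Fatty acid synthase Fasn (−0.49 ± 0.70), the carnitine transferase Cpt1a (0.21 ± 0.19), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.22 ± 0.79), and the hormone gene Fgf21 (−0.74 ± 0.56) had adjusted p values of 0.840, 0.724, 0.588 and 0.657. Without wild-type 2 the log2 fold change of Cyp2e1 was 0.99 and that of Cyp7a1 2.65, and without knockout 2 that of Fgf21 was −1.70. Without wild-type 3 those of Fasn, Cpt1a and Aldh2 were −0.98, 0.39 and 0.0156. Of 28 genes chosen before the data were examined for their place in alcohol-fed liver, 27 were tested and 0 passed in edgeR over all genes, while DESeq2 called 4. An unadjusted p under 0.05 was found for 8, all lower in the knockout: Spp1, S100a9, Ccl2, Il1b, Tnf, Adgre1, Col1a1 and Timp1. Ly6g, a neutrophil marker, had at most 1 count per library and was not tested, and S100a8 gave 0.794 ± 0.356 against 0.536 ± 0.412 CPM.

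The knockout allele was made in embryonic stem cells and moved into C57BL/6, so genes near Cd44 were compared with all others. Within 10 Mb of Cd44, 0 of 68 tested genes passed in edgeR against 1 of 14076 elsewhere, while 4 of the 68 had an unadjusted p under 0.01 and DESeq2 called 3 of 67. A single edgeR call is too few to test for enrichment. Within 20 Mb the edgeR count was 1 of 223, Disp2, against 0 elsewhere, and DESeq2 called 12 of 225 against 274 of 13943 (Fisher's exact p = 0.0021). Without knockout 1, edgeR called 1 gene within 10 Mb. Genes with low p within 30 Mb went both ways: Fibin (2.67 ± 0.126 against 15.1 ± 8.56 CPM, 2.50 ± 0.48), Exd1 (1.20 ± 0.21), Mga (0.60 ± 0.12) and Prnp (0.56 ± 0.11) were higher in mean, and Cd59a (−1.27 ± 0.24) and Chp1 (−1.07 ± 0.18) lower. These genes were chosen after their values were seen, each had an adjusted p of 0.217 in edgeR, and DESeq2 called all of them. Cd59a and its neighbour Cd59b are close copies and can share reads.

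**Figure D3:**
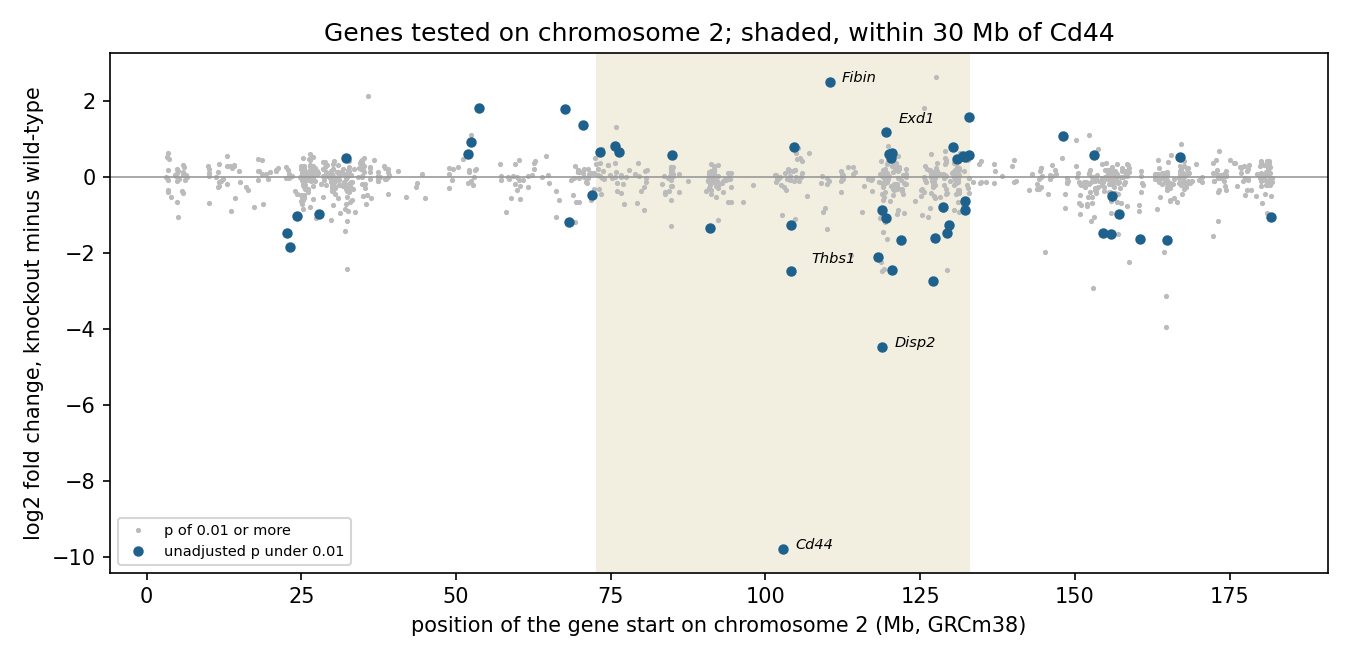
Log2 fold change, knockout minus wild-type (y axis), of each gene tested on chromosome 2 by the position of its start (x axis, Mb, GRCm38), with genes of unadjusted p under 0.01 as larger blue points and the 30 Mb on each side of Cd44 shaded. Besides Cd44 at −9.78 and Disp2 at −4.46, low p values occur on both sides of 0, such as Fibin at 2.50.

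Wild-type 3 stood apart from the other 5 libraries. On the first principal component, which held 40.6% of the variance, it was at −63.4 while the others lay between −15.1 and 29.5. Its correlation of log CPM across genes with the other libraries was 0.945 to 0.959, against 0.964 to 0.977 for pairs with wild-type 1 or 2 and without wild-type 3, and 0.980 to 0.981 among the knockout libraries; genes are not independent replicates. No pair of libraries agreed within sampling noise (smallest chi-square per degree of freedom 21.3). All 6 libraries had 8687 to 11072 counts of Xist, the X-inactivation transcript, and 0 counts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, which allows up to 3 counts per gene and library. Without wild-type 3, edgeR called 2 genes and camera 22 lists, of which 16 were among the 19 lists called with all libraries.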

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

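The windows of 30 Mb around Cd44, the DESeq2 count within 20 Mb and the lists without genes near Cd44 were chosen after seeing the data. The count of 2 genes was the same with RLE scaling, the CPM filter, protein-coding genes only, or a log2 fold change of at least 1, and moved to 6 with no low-count filter, 1 with the older quasi-likelihood fit, 1 at a threshold of 0.01, 287 with DESeq2, 0 with limma-voom and between 0 and 151 without each library in turn (151 without wild-type 2); the cause was not tested. With the mouse number as a replicate block 1 gene passed. Over all genes the numbers showed no pairing, as deviations of same-numbered mice correlated at −0.016, −0.018 and −0.010. Shared handling that moved few genes is not excluded by this. Muscle genes, a list of 4 tested members, stood highest in the mice numbered 2. Their medians were 1.79 in wild-type 2 and 1.13 in knockout 2 from the mean of all libraries, and negative in every other library. This list was picked after its values were seen, and the cause was not tested. Cd44 was lower in all fits, at −8.996 with limma-voom (adjusted p = 0.283) and −11.73 to −9.20 without each library in turn, where each fit without a knockout library has fewer samples and missed the threshold. The 19 lists became 17 to 26 without each library in turn, 21 with the block, 18 without genes within 30 Mb of Cd44, where the inflammasome call was lost, and 0 with an estimated correlation, the cause of which was not tested. Genes called near Cd44 were 1 within 20 Mb, 3 with DESeq2 within 10 Mb, 12 with DESeq2 within 20 Mb, and 0 to 1 without each library in turn. The share of genes near Cd44 with unadjusted p under 0.01 was 7.89%, 5.88% and 7.17% in windows of 5, 10 and 20 Mb (Fisher's exact p = 0.194, 0.352 and 0.0234), and 4.52% to 10.4% within 30 Mb without each library in turn.

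The direction camera gives a list reversed mainly where a library was left out, and the cause was not tested. The ranges of the median log2 fold change over the fits without each library in turn were −0.28 to 0.13 for liver endothelial genes, −0.0229 to 0.24 for amino acid and urea cycle genes, −0.0312 to 0.14 for ribosomal protein genes, −1.53 to 1.12 for muscle genes, −0.22 to 0.33 for T and NK cell genes, −0.0464 to 0.18 for acute-phase genes, −0.85 to 0.0354 for erythroid and platelet genes, −1.28 to 0.31 for adipocyte and mesothelial genes, −0.22 to 1.65 for B and plasma cell genes, −0.0895 to 0.55 for pericentral hepatocyte genes, −0.31 to 0.23 for lipogenesis genes and −0.24 to 0.88 for female-biased liver genes. Camera's direction for muscle genes, a list of 4 members whose main median was −0.50 with direction up, was down with no filter (median −0.59), with the replicate block (−0.29) and on camera ranks (−0.50), so the median kept its sign there. For T and NK cell genes it reversed with the replicate block (0.0074). Of the lists, 23 fits in all reversed, 32 lost a call and 32 gained 1, with 486 on the same side. Of 82 named genes other than Cd44, 982 fits kept direction and side, 72 gained a call, 7 lost it (all for Disp2), and Cyp2e1 reversed (−0.0153 to 0.99 without each library in turn). Depth limits genes under a few CPM, such as Ly6g, S100a8 and Tnf.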

Other observations

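The tests written after the results they weigh were seen are the splits for the gene count, the fit without wild-type 3, the comparison of cytokine with macrophage genes, and the tests of wild-type 3; the 30 Mb window around Cd44 was also chosen after seeing the p values along chromosome 2.

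Other metabolic and immune lists did not pass with all 6 libraries. Of 28 glycolysis and gluconeogenesis genes, 18 had a lower mean in the knockout (median log2 fold change −0.22, camera adjusted p = 0.0982, 0.360 with an estimated correlation), with 0 passing over all genes and 1 adjusted over the list alone, the pyruvate kinase Pkm (42.9 ± 7.18 against 21.9 ± 4.96 CPM, n = 3 each, −0.97 ± 0.20); Hk3, a hexokinase of myeloid cells, gave −1.27 ± 0.35 and is uncertain because it overlaps Unc5a on the opposite strand. The glycolysis list passed, lower in the knockout, without wild-type 3 (adjusted p = 0.000630) and without knockout 2 (0.0492). Over all genes DESeq2 called 2 of its members, and 1 each of the fatty acid oxidation and MHC class II lists, all lower. Lipid droplet and lipid uptake genes did not pass as a list (median −0.08, adjusted p = 0.152, 0.360 with an estimated correlation), with 0 passing in edgeR over all genes and 1 adjusted over the list alone, lipoprotein lipase Lpl, at 111 ± 69.4 in wild-type and 18.5 ± 5.29 CPM in knockout livers (−2.59 ± 0.48). DESeq2 called Lpl over all genes (adjusted p = 1.25e-07). Wild-type 3 was highest for Lpl, and the log2 fold change was −1.98 without it; the list passed without wild-type 1 (adjusted p = 0.0465). Fatty acid oxidation and PPARA target genes were short of the threshold (median −0.11, adjusted p = 0.0664, 0.677 with an estimated correlation), with 0 passing over all genes and 1 adjusted over the list alone, the mitochondrial carrier Ucp2 (−0.73 ± 0.15); the list passed without wild-type 1 (adjusted p = 0.0354), without knockout 3 (0.00114), with the mouse number as a block (0.0432), with no low-count filter (0.0419) and with camera on ranks (0.0345).

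MHC class II and antigen presentation genes went both ways (median −0.22, adjusted p = 0.156, 0.641 with an estimated correlation; 0.00543 without knockout 2), with 0 passing over all genes and 0 adjusted over the list alone. The class II loading gene H2-DMb1 gave −1.07 ± 0.29 and the lysosomal protease Ctss −0.88 ± 0.24, while the interferon-inducible peptide transporter Tap1, uncertain because it overlaps Psmb9, gave 0.58 ± 0.19. Endoplasmic reticulum stress genes had a median of 0.13 (adjusted p = 0.205, 0.431 with an estimated correlation), with 0 passing over all genes and 0 adjusted over the list alone, and their medians in the 3 wild-type mice (−0.04, −0.07 and −0.16) did not overlap those in the 3 knockout mice (0.09, 0.05 and 0.11), a separation chance gives in 10% of lists. Hspa5, the chaperone BiP, gave 0.37 ± 0.15 and Dnajc3 0.31 ± 0.13. The gene models without a name showed no call in edgeR, with 0 of 111 tested passing, 14 at an unadjusted p under 0.05 and a smallest adjusted p of 0.244; other tools were not run on them.

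Macrophage, cytokine and matrix genes were lower in mean in the knockout. The list calls rest on the preset correlation, and 0 of 41 lists passed with an estimated correlation. The 10 splits of the 6 libraries are too few for a share under 0.05: 5 of them, the real one included, gave as many lists as the real 19, with 25 the highest of the others, and 1 of 10, the real one, gave as many as 2 genes, with 0 the highest of the others. The gene count is no test of chance, because the targeted gene Cd44 is 1 of the 2 and splits that mix the genotypes can hardly call it. Of the 5 lists weighed (monocyte and infiltrating macrophage, Kupffer cell, cytokine and chemokine, toll-like receptor and NF-kB, extracellular matrix and fibrosis), 5 stayed lower without wild-type 3, and 5 stayed lower after a trend on GC content, length and level was taken out. Both checks used the preset correlation, at which the other splits called 8 to 25 lists. They show that the calls did not need wild-type 3 or that trend, but cannot exclude either as a source. A smaller share of macrophage RNA in the knockout livers may account for part of the lower values: cytokine and chemokine genes differed from macrophage markers by −0.0242 in median log2 fold change, but the 95% bootstrap interval of −0.46 to 0.56 is wide, and genes are not independent. Fewer macrophages and less transcription per macrophage were not separated, and an effect of the genotype stays open as a hypothesis.

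Low p values were more frequent within 30 Mb of Cd44 than elsewhere. The excess was not clear closer to the gene. Within 10 Mb, the window of the planned test, 4 of 68 genes (5.88%) had an unadjusted p under 0.01 (Fisher's exact p = 0.352), and within 5 Mb 7.89% (p = 0.194). Within 30 Mb, 30 of 365 genes (8.22%) had an unadjusted p under 0.01 against 3.90% elsewhere (Fisher's exact p = 0.000198), and none (0%) of 6133 overlapping runs of 365 neighbouring genes on the other chromosomes had as high a share in the test for alleles linked to Cd44, with 6.58% the highest. Genes with a log2 fold change above 0 showed the excess too (14 of 166 against 3.17% elsewhere, Fisher's exact p = 0.00109), so it was not limited to lower genes. This cannot exclude myeloid and cell cycle genes that happen to lie there as a source. The window came from these same p values, and neighbouring genes are not independent. Alleles of the embryonic stem cell strain that stayed linked to Cd44 are a candidate explanation for Disp2, Fibin, Exd1 and Chp1, and may also bear on Sirpa, Thbs1, Il1b and Pcna. No sequence variants were analysed here, and the window was chosen from these p values, so this remains a hypothesis.

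Wild-type 3 lay apart from the other libraries. A male mouse or sex mix-up is argued against by its Xist level, 0.7997 times the lowest of the others, with 0 Y-linked counts, and a swap with a knockout library by its Cd44 level of 28.9 CPM. Its gene count lay within the range of the others, while its share of Alb reads (7.01%) and its TMM factor (1.10) lay 0.637 and 0.545 ranges outside it, so a difference in RNA composition stays open. Its high Lcn2 and cell cycle genes and low lipogenesis and female-biased liver genes leave a stronger response of that mouse to ethanol, or differences in sampling, as untested explanations.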
